A study of Mus musculus with 2 samples.

How the data were processed

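Total RNA of the heart was sequenced from mouse embryos of the B6NCrl strain, a C57BL/6 substrain, at embryonic day 14.5. There were 2 libraries in 1 group, the E14.5 heart, and the labels describe them as biological replicates 1 and 2, each from a single heart of a different collection day in July (day 15 for replicate 1 and day 17 for replicate 2). The labels give the sex of both as a pool of male and female. RNA was extracted with the mirVana method, 10 ng was used per library, the RNA size range was above 200 nt, and spike-in RNAs were added, all per the labels' protocols. A Smart-seq document is cited as the general protocol, per the labels. Both labels give pup 1 of pregnant 2, on different days, and embryo and collection day differ together between the libraries.

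Each library had a gene table and a transcript table. The genome was mm10 and the annotation GENCODE M4, per the submitters' processing notes. The aligner, the quantification tool and their versions are not given in the sources used here, nor is the use of strand. The column names are those of RSEM output. The expected counts are estimated counts per gene that share reads among genes they fit and are not scaled by depth, per the file headers and values of the deposited tables. The TPM values were scaled by the authors to 1e+06 over all rows, spike-ins included, with an effective length that was 99 nt below the length. The FPKM values were also computed by the authors and were used here only as an alternative. Posterior mean counts and their standard deviations are further estimates in the deposited tables.

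The gene tables had 69691 rows, of which 43346 carried an Ensembl gene identifier, 96 were ERCC spike-ins, 26248 carried only a number and 1 was phiX. Gene names and positions came from GENCODE M21 on the same assembly (GRCm38), a later annotation than that of the tables, matched on the identifier without its version suffix. A symbol was found for 42462 gene rows (98.0%), and rows without one held 0.150% and 0.152% of the gene counts. All analyses of genes used the rows with an Ensembl identifier.

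The total expected count was 2.85e+07 in replicate 1 and 2.90e+07 in replicate 2, and 2.75e+07 and 2.79e+07 lay on gene rows. Over 16387 genes with a mean count of at least 10 the chi-square between the libraries averaged 14.2 per gene. This is above counting noise alone, as separate embryos can give. For a given fold the chi-square grows with the count, so a few abundant genes can weigh heavily in this mean. Levels are given as mean TPM ± SD over the 2 libraries. The median of a list is that of its members' mean TPM, its SD is that of the medians of the 2 libraries, and it can lie outside both. Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, with TMM scaling and filterByExpr. This gave the biological coefficient of variation (the relative spread of a gene between the 2 libraries beyond counting error). It holds technical noise of each library as well as differences between the embryos. With 1 library per embryo no p-value across genes was computed, and a sign test over 2 libraries cannot go below 0.5. The fold between the libraries used TMM-scaled counts with a prior of 0.5, written as log2 of replicate 2 over replicate 1. Its exact 95% interval (Clopper-Pearson on the share of the sum of both counts) covers counting error only, and reads are not independent molecules. A count of 0 was set against the 3 counts per library that it allows. Each gene was also set against the 2.5 to 97.5 percentile range of genes of like count. Shares of counts have Wilson 95% intervals, with the same limit.

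Before the data were examined, 34 gene lists, 22 pairs of related genes, 22 genes for isoform shares and the rule for named genes were fixed. The lists hold 612 places, of which 607 matched a gene row, and some genes are in more than 1 list. The rule names up to 5 members of highest mean TPM per list, members at least 2-fold apart with a mean count of at least 50, the pairs and isoform genes (in full only the 8 largest ratios, or an SD above the mean), the 20 most abundant genes, the 10 largest differences per direction with a mean count of at least 200 and a symbol, all sex-linked list members, and members of other-tissue lists at a TPM of at least 1 in both libraries. A pair counted as different when both libraries had the same sign and the mean log2 ratio was beyond the 95th percentile of the replicate differences of single genes. A list stood apart when its median difference lay outside the 2.5 to 97.5 percentile range of 10000 random lists of the same size matched on expression in 20 bins. Members of a list are co-expressed, which random lists are not, so these ranges understate the spread of a list. Of 32 lists tested, 1.6 would be expected outside by chance if genes were independent. The number for co-expressed and overlapping lists was not estimated. The lung list and the thymus list had too few members at a mean count of at least 10 to be tested.

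Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The steps were tested on simulated counts for 16407 genes with the mean counts of this comparison, of which 200 were changed. Every simulated gene had a coefficient of variation of 12%. In the data the common value was 8.83%, and it was higher at low expression. The rates of recovery and of false calls therefore belong to the simulation and were not estimated for these data. Of the changed genes with a mean count of at least 100, the fold step recovered 96.0% of 75 genes set to a log2 change of 1.5 and 100% of 76 genes set to 3, and it called 4 of 11815 unchanged genes. Of 200 lists of unchanged genes, 10 fell outside the range. All 200 lists with 12 of 20 genes raised by 1.5 or 3 (log2) did. With most members raised that far the list median had to lie high, so recovery of smaller list differences was not tested. A coefficient of variation of 12% was estimated as 11.9% with no gene changed and as 16.7% with the 200 changed genes left in.

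The alternatives were other thresholds, FPKM, other scalings (DESeq2 1.42.0 size factors, total counts, spike-in counts), unmatched random lists, other count minimums, and each library alone where that gives a value. Spike-in scaling moved all genes by 0.11 (log2) towards replicate 2 against TMM, and differences are given relative to the TMM centre. Alternatives without sex-linked genes, without X and Y genes, without haemoglobin genes, with posterior mean counts for the 2-fold genes and with GC and length correction were chosen after seeing the data. Rows identified only by a number entered no comparison. Values of some single genes that the rule names are not reported here.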

Results

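Total RNA from 2 single mouse hearts at embryonic day 14.5 was sequenced, 1 library per heart. At this stage the chambers have formed and are being divided by septa, while valves and coronary vessels are still developing. The series holds 1 group, so the measurements describe the transcriptome of the E14.5 heart and how far the 2 embryos differed. Of the gene rows, 13635 reached a TPM of at least 1 in both libraries (14091 in replicate 1 and 14277 in replicate 2). Of these genes, 12202 were protein coding and 189 were lincRNAs. A TPM of at least 100 was reached by 1289 genes in both libraries.

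Genes of the contractile apparatus were among the most abundant. Of 31 sarcomere genes, 30 were at a TPM of at least 1 in both libraries, and the median of the list was 707 TPM in replicate 1 and 696 TPM in replicate 2. The most abundant was Actc1, cardiac alpha-actin, at 11908 ± 426 TPM. Its gene lies on chromosome 2 from 114047282 to 114053548 (GRCm38, GENCODE M21). It was followed by the ventricular regulatory light chain Myl2 at 8249 ± 438 TPM, the cardiac troponin T gene Tnnt2 at 5917 ± 298 TPM, the atrial regulatory light chain Myl7 at 4964 ± 1149 TPM and the tropomyosin gene Tpm1 at 4111 ± 78.5 TPM. All 15 calcium handling genes were detected, with a median of 114 ± 5.66 TPM. Phospholamban (Pln), which restrains the calcium pump, was at 724 ± 36.1 TPM, and the pump gene Atp2a2 was at 353 ± 8.28 TPM. Calr was at 397 ± 15.7 TPM, Sln at 360 ± 93.1 TPM and Casq2 at 357 ± 28.2 TPM. Of 22 ion channel and conduction genes, 19 were detected. Gja1, which encodes the gap junction protein connexin 43, led this list at 368 ± 12.7 TPM, ahead of Kcne1 (151 ± 3.79 TPM) and Gjc1 (42.4 ± 0.714 TPM). The cardiac transcription factor list also holds cofactor genes such as Smyd1. All 24 members were detected, with a median of 24.4 ± 2.00 TPM. Nkx2-5 (136 ± 2.12 TPM), Gata4 (123 ± 0.495 TPM), Smyd1 (110 ± 5.85 TPM) and Mef2a (101 ± 3.78 TPM) were the highest of them.

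**Figure D1:**
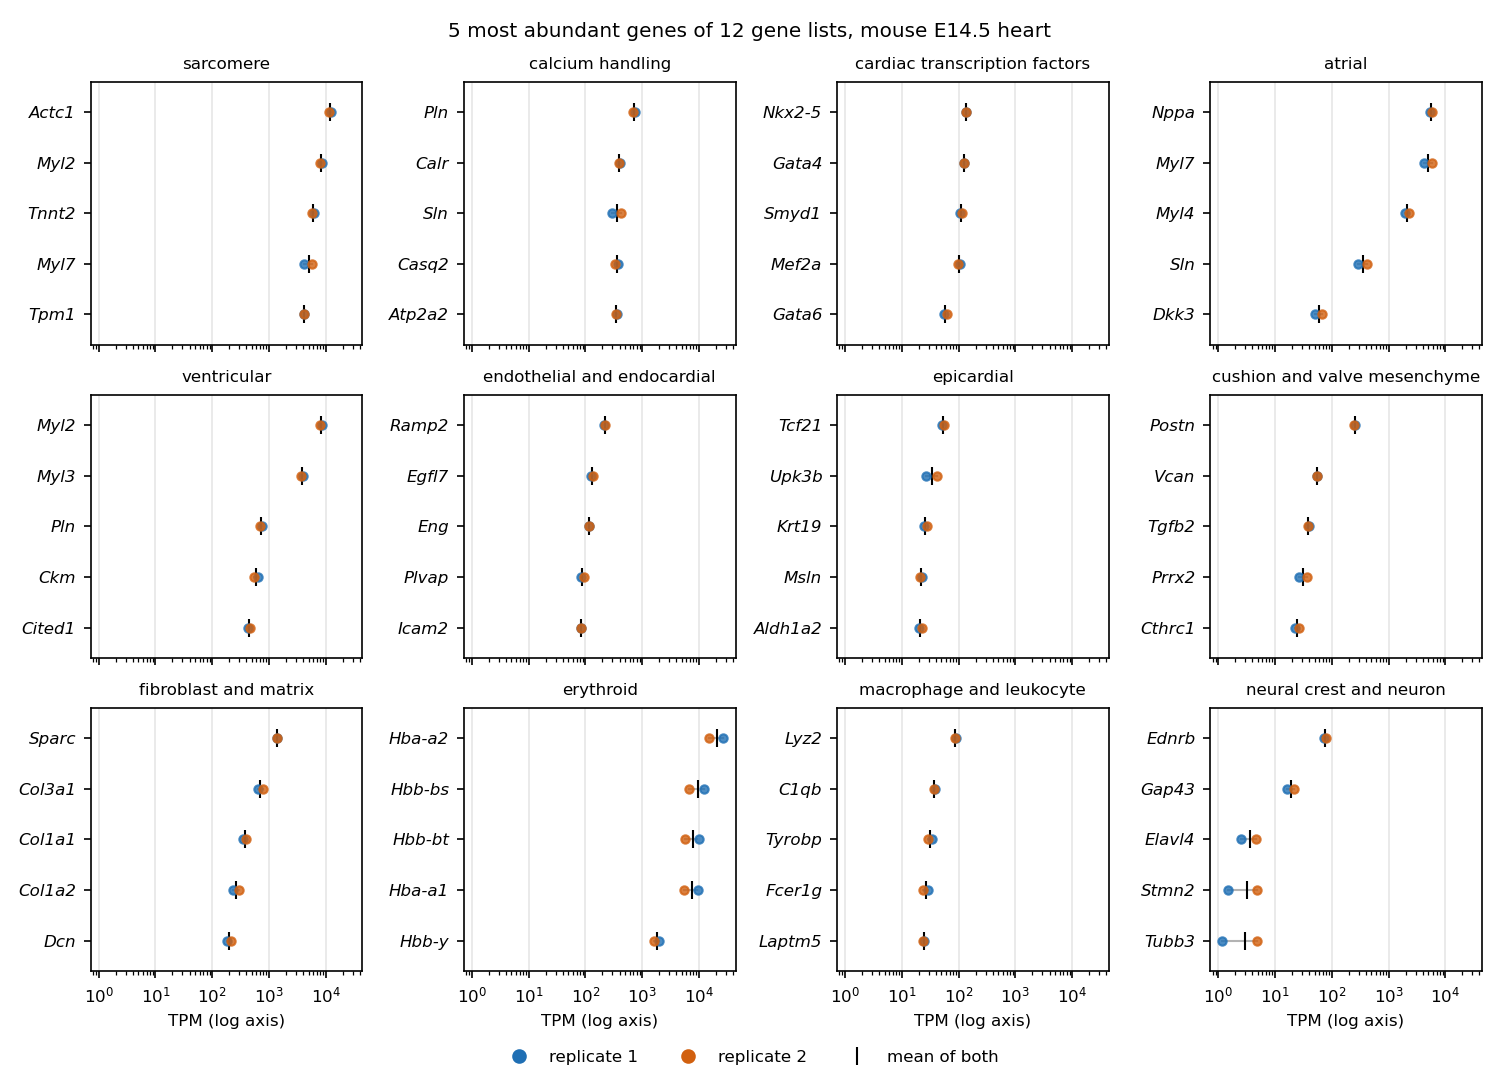
TPM on a log axis of the 5 most abundant members of 12 gene lists, with 1 point per heart (blue, replicate 1; orange, replicate 2) and a bar at their mean. Sarcomere genes lie above 1000 TPM and genes of the transcription factor list near 100 TPM. The haemoglobin genes and Stmn2 and Tubb3 show the widest gaps between the hearts.

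Genes of both chamber types and of the non-muscle cells of the heart were measured. All 15 atrial genes were detected, led by Nppa, which encodes atrial natriuretic peptide, at 5711 ± 315 TPM, and by Myl7 and Myl4 (2144 ± 242 TPM). All 13 ventricular genes were detected, with Myl2 and Myl3 (3786 ± 155 TPM) highest, and with Ckm at 597 ± 70.4 TPM and Cited1 at 444 ± 34.1 TPM. All 22 endothelial and endocardial genes were detected, with a median of 39.4 ± 0.262 TPM. Ramp2 (219 ± 5.17 TPM), Egfl7 (132 ± 8.99 TPM) and Eng (115 ± 0.608 TPM) were the highest. All 15 measured epicardial genes were detected, with Tcf21 at 53.5 ± 3.76 TPM and Upk3b at 34.1 ± 10.5 TPM. Of 18 cushion and valve mesenchyme genes, 16 were detected, led by periostin (Postn) at 256 ± 6.40 TPM and versican (Vcan) at 55.6 ± 0.735 TPM. Fibroblast and matrix genes had a median of 49.1 ± 2.15 TPM over 22 members, with 21 detected, and Sparc (1395 ± 13.3 TPM), Col3a1 (708 ± 104 TPM) and Col1a1 (373 ± 34.9 TPM) were the highest. Of 14 smooth muscle and pericyte genes, 13 were detected. Acta2 was at 1032 ± 42.0 TPM, elastin (Eln) at 173 ± 61.2 TPM and Cnn1 at 111 ± 6.72 TPM, while Myh11, a marker of mature smooth muscle, was at 0.91 ± 0.679 TPM.

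Blood and immune genes were also present. Of 16 erythroid genes, 14 were detected, and the adult haemoglobin gene Hba-a2 had the highest mean of any gene, 20879 ± 8405 TPM. The embryonic gene Hbb-y was at 1804 ± 221 TPM. All 16 macrophage and leukocyte genes were detected, with a median of 12.0 ± 1.94 TPM and with Lyz2 (87.6 ± 2.93 TPM) and C1qb (37.4 ± 1.53 TPM) highest. Of 18 neural crest and neuron genes, 7 reached a TPM of at least 1 in both libraries, led by Ednrb (76.6 ± 3.07 TPM) and Gap43 (18.9 ± 3.91 TPM).

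Lists for neighbouring and other tissues were near the lower limit. None of the 9 lung and airway epithelium genes and none of the 7 thymus genes reached a TPM of 1 in both libraries, at a depth where 1 count on a 1 kb effective length equals 0.0478 and 0.0475 TPM. Of 11 liver genes, 3 were at or above 1 TPM in both, namely Trf (33.4 ± 1.95 TPM), Apoa2 (4.12 ± 0.00707 TPM) and Ahsg (2.58 ± 1.44 TPM). Of 14 skeletal muscle genes, 4 were, namely Tnni2 (21.3 ± 3.73 TPM), Mylpf (10.6 ± 2.21 TPM), Tnnt3 (3.06 TPM in replicate 1 and 4.52 TPM in replicate 2) and Chrng (1.18 ± 0.0495 TPM).

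Energy metabolism was represented at high levels by both oxidative and glycolytic genes. The 28 nuclear-encoded respiratory chain genes had a median of 774 ± 6.61 TPM, with Atp5b at 5088 ± 50.5 TPM. The 13 mitochondrially encoded protein genes had a median of 2600 ± 54.0 TPM, with mt-Atp6 at 12138 ± 229 TPM, although several share reads with copies on chromosome 1. The posterior SD of mt-Atp6 was 20140 and 19880 reads on counts of 149782 and 146606, which the SD between libraries does not cover. The 17 glycolysis genes had a median of 598 ± 7.91 TPM, with Gapdh (3943 ± 269 TPM) and Ldha (2403 ± 61.3 TPM) highest. The 22 fatty acid oxidation genes had a median of 152 ± 8.04 TPM, and the fatty acid binding protein gene Fabp3 (1213 ± 12.2 TPM) led them. Hypoxia genes had a median of 16.3 ± 0.880 TPM, with Bnip3 at 225 ± 25.4 TPM. Proliferation genes were expressed throughout both lists. All 20 mitosis genes (median 54.6 ± 2.32 TPM) and all 20 DNA replication genes (median 45.6 ± 3.43 TPM) were detected, with Birc5 at 182 ± 6.43 TPM, Cdk1 at 268 ± 8.51 TPM and Rrm2 at 155 ± 11.5 TPM. Of 14 replication-dependent histone genes, 11 were detected, with a median of 3.29 ± 0.689 TPM. These transcripts lack poly(A) tails, and most members share sequence. Outside the list, and chosen after seeing the values, the histone gene Hist1h2ap was at 1237 ± 33.7 TPM. The list median therefore covers only the listed genes, and low capture of histone transcripts in general cannot be read from it.

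Genes known to rise in the heart around birth were already measured together with fetal genes. The 18 genes that rise with cardiac maturation had a median of 323 ± 3.78 TPM, led by Tnni3 (2404 ± 64.4 TPM), Fabp3 and Myh6 (914 ± 75.5 TPM). The 19 that fall had a median of 89.4 ± 0.0636 TPM, led by Tnni1 (3912 ± 4.75 TPM), Myh7 (2653 ± 174 TPM) and Mest (2099 ± 75.4 TPM). All 16 imprinted genes were detected, among them Igf2 (1244 ± 25.7 TPM), H19 (875 ± 49.9 TPM) and Cdkn1c (402 ± 63.5 TPM). All 20 Notch, neuregulin and BMP signalling genes were detected, led by Id3 (212 ± 26.4 TPM) and Id2 (203 ± 21.8 TPM). Of 23 immediate early and stress genes, 19 were detected, led by Dnajb1 at 39.1 ± 0.728 TPM, with medians of 13.9 and 13.7 TPM in the 2 libraries. The 39 ribosomal protein genes had a median of 558 ± 48.7 TPM, led by Rps19 (1224 ± 131 TPM). Of 11 nuclear and structural noncoding RNAs, 8 were detected, led by Malat1 at 5906 ± 101 TPM.

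Related genes with chamber-specific, stage-specific or tissue-specific partners were compared within each heart. All 22 pairs differed by the fixed rule, for which the limit was a log2 ratio of 0.54, or 1.45-fold. This limit is the replicate spread of single genes, so 2 unrelated genes can pass it as well. No rate for random pairs was computed, so the count of 22 is no evidence about these pairs as a group. With 2 libraries no sign test can pass a threshold. The first-named gene was the higher one in 15 pairs and the second in 7. The largest ratio was that of the cardiac ryanodine receptor Ryr2 over the skeletal muscle form Ryr1, with a log2 ratio of 9.08 ± 0.41 (SD, n = 2), although Ryr1 had a mean of only 0.05 TPM. Atp2a2 exceeded Atp2a3 by 7.38 ± 0.10, cardiac actin Actc1 exceeded skeletal actin Acta1 by 6.01 ± 0.07, and Nppa exceeded Nppb by 5.16 ± 0.18. The adult gene Hba-a1 exceeded the embryonic Hba-x (ratio -4.78 ± 0.34 for Hba-x over Hba-a1). Tnnt2 exceeded the slow skeletal form Tnnt1 by 3.89 ± 0.07, Gja1 exceeded Gja5 by 3.53 ± 0.13, and Cox8a exceeded the muscle form Cox8b by 2.76 ± 0.04.

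Among the other pairs, the fetal member was ahead in the myosin and troponin comparisons. Myh7 was 2.90-fold above Myh6 and Tnni1 was 1.63-fold above Tnni3. Slc2a1, the constitutive glucose transporter, was 6.18-fold above the insulin-responsive Slc2a4. The ubiquitous forms exceeded the muscle forms for Cox7a2 over Cox7a1 (1.87-fold), Cox6a1 over Cox6a2 (1.70-fold) and Eno1 over Eno3 (3.80-fold). Hk1 was 3.54-fold above Hk2, and Pfkp was 1.76-fold above Pfkm. In contrast, the muscle forms Cpt1b and Ckm were 6.64-fold above Cpt1a and 2.94-fold above Ckb. Ldha was 2.13-fold above Ldhb, and Hbb-bt was 4.18-fold above Hbb-y. The ventricular light chains were ahead of the atrial ones, Myl3 by 1.77-fold over Myl4 and Myl2 by 1.68-fold over Myl7. In replicate 2 alone the Myl7 over Myl2 ratio was -0.46, inside the limit, against -1.04 in replicate 1.

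**Figure D2:**
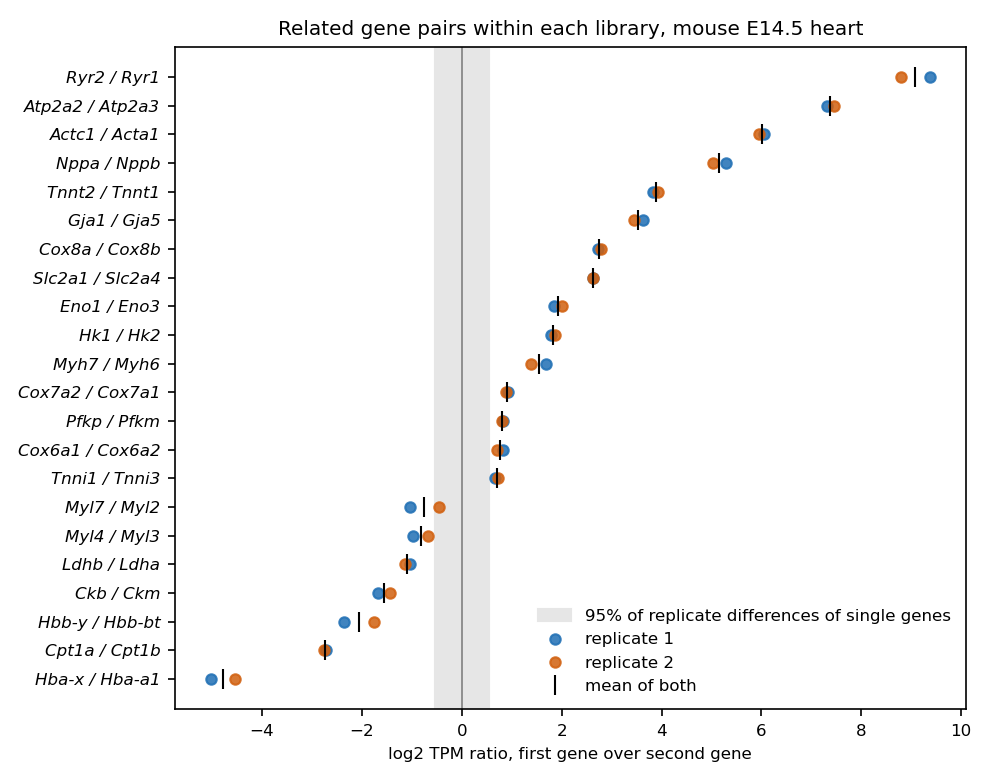
Log2 TPM ratio of 22 pairs of related genes within each heart (blue, replicate 1; orange, replicate 2; bar, mean). The grey band spans the 95th percentile of replicate differences of single genes, 0.54 on either side of 0. The means run from -4.78 for Hba-x over Hba-a1 to 9.08 for Ryr2 over Ryr1.

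Transcript use was compared between the 2 hearts for 22 genes known for alternative splicing or promoters. Of the 20 with more than 1 annotated transcript, the same one led in both libraries for 19, and it held at least 50% of the gene's TPM in 15. For Tpm1 the transcript Tpm1-205 held 94.3% ± 0.00609 of TPM among 21 annotated transcripts. Pkm-202 held 75.2% ± 0.275, Tnnt2-207 held 57.0% ± 0.0689, Mef2c-203 held 52.1% ± 0.892 and Postn-203 held 48.0% ± 0.0944. The widest spread was for Vegfa-211, with 41.3% in replicate 1 and 49.4% in replicate 2. For Fn1 a retained-intron transcript and another one changed places by TPM, with a mean share of 32.7% ± 0.186 for the former. By estimated counts the same transcript led in both libraries for all 22 genes. Shares of TPM favour short transcripts, and by estimated counts the same transcripts of Ttn, Cacna1c, Mef2c and Pdlim5 held only 7.80%, 17.2%, 36.8% and 45.9%, and that of Ldb3 held over 2-fold less than by TPM. Other leading transcripts held more by estimated counts than by TPM, among them those of Mef2a (83.7%) and Camk2d (59.4%). The leading transcripts of Ttn and Cacna1c were short transcript models of 2159 and 954 nt, with shares by TPM of 62.5% ± 1.74 and 70.0% ± 0.761. Slc8a1-201 held 99.5% ± 0.709 and Bin1-202 held 96.9% ± 0.0372. Myl6 and Pdlim3 had 1 transcript each in the annotation used. The remaining genes (Mef2a, Fhl1, Pdlim7, Pdlim5, Rbfox2, Actn1, Mef2d, Ldb3 and Camk2d) had leading shares by TPM from 45.6% for Camk2d-202 to 69.2% for Mef2a-208.

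The 20 most abundant genes comprised haemoglobin, sarcomere, mitochondrial and structural RNA genes, Nppa and chromosome 1 pseudogenes. Besides those above, they were Hbb-bs (9430 ± 3756 TPM), Hbb-bt (7834 ± 3167 TPM), Hba-a1 (7642 ± 3009 TPM), mt-Atp8, mt-Rnr2, mt-Cytb, mt-Co1, mt-Nd1, Rn7s1, Rn7s2, Gm42418, Gm28437 and Gm29216. Gm42418, a lincRNA locus on chromosome 17 known to carry ribosomal RNA sequence, was at 9965 ± 697 TPM. Gm28437 (14600 ± 135 TPM) and Gm29216 (6132 ± 320 TPM) are unprocessed pseudogenes on chromosome 1 that copy mitochondrial genes. All 25-mers of Gm28437 occur in mt-Co3, and 97.2% of those of Gm29216 occur in mt-Co1. The posterior SD of the count of Gm28437 was 59586 and 62454 reads against estimates of 207591 and 211431, so its split from mt-Co3 is not determined, while that of Gm29216 was 218 and 219 reads. Summed with their copies, mt-Co3 and mt-Co1 differed between the hearts by -0.01 (log2) each. Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and Rn7s1 and Rn7s2 are likewise near-identical pairs.

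Haemoglobin genes took a smaller share of the counts in replicate 2. They held 2.24% in replicate 1 (Wilson 95% interval 2.24 to 2.25) and 1.26% in replicate 2 (1.26 to 1.27). The mitochondrially encoded genes held 3.74% and 3.84%, or 4.90% and 5.00% with the chromosome 1 copies. The sarcomere list held 6.67% and 6.39%. The replication-dependent histone list held 0.00722% and 0.00864%. The spike-ins held 3.74% and 3.55%, and the 100 most abundant genes held 24.4% and 23.5%.

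The 2 hearts gave closely similar profiles. Across 14202 genes with a mean of at least 1 TPM, Pearson's r of log2 (TPM + 1) was 0.986 and Spearman's rho was 0.987. These are correlations across genes, which are not independent replicates. The SD of the replicate difference over these genes was 0.34 (log2). The common biological coefficient of variation was 8.83% over 15735 genes, and 8.25% without Xist, the only sex-linked list member that passed the filter. It was not the same at all expression levels. As a fraction, where the common value is 0.088, the trended value had a median of 0.204 in the lowest decile of expression. In the top decile it was 0.077, and 0.057 without Xist. Over 64 spike-ins with a mean count of at least 10, the SD of the replicate difference was 0.36, inside the 0.29 to 1.00 of 1000 random gene sets of like count. Over 45 spike-ins with at least 100 counts it was 0.11, below the 0.14 to 0.41 of matched gene sets.

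Few genes differed by 2-fold or more between the hearts. Of 11958 genes with a mean count of at least 100, 51 did (0.426%), with 37 higher in replicate 2 and 14 higher in replicate 1 (52 and 10 with spike-in scaling, and 5 and 6 at a mean count of at least 500). There is no test of embryos here, since each is 1 library. Lowering the count minimum to 10 gave 659 genes of 16387 (4.02%).

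Genes higher in replicate 1 included 4 Y-linked genes and 3 members of the erythroid list. The secreted phosphoprotein gene Spp1 was 5.86-fold higher (95% interval 5.16 to 6.70), with 1555 counts against 275. Gpnmb was 4.56-fold higher (3.65 to 5.81), and Lgals3, which encodes galectin 3, was 2.88-fold higher (2.31 to 3.63). The red cell membrane gene Slc4a1 was 2.18-fold higher (1.94 to 2.46), and the haem synthesis gene Alas2 was 2.06-fold higher (1.96 to 2.16). The lincRNA Gm26735 was 2.10-fold higher (1.77 to 2.49).

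Genes higher in replicate 2 included the transcription factor genes Shox2 and Isl1 and 3 members of the neural list. Shox2, a regulator of the sinus node (chromosome 3, 66971727 to 66981771), was 3.23-fold higher (2.68 to 3.93), with 477 counts against 142. Isl1, a factor of the second heart field and sinus node, was 3.22-fold higher (2.40 to 4.44). The smooth muscle myosin gene Myh11 was 3.10-fold higher (2.32 to 4.25). The neuronal genes Tubb3, Stmn2 and Ngfr were 3.86-fold (2.79 to 5.55), 3.36-fold (2.52 to 4.59) and 2.30-fold (1.73 to 3.11) higher. The Wnt receptor gene Fzd7 was 2.82-fold higher (2.31 to 3.46), Clca3a2 2.64-fold (2.14 to 3.25), Mdfi 2.36-fold (2.00 to 2.82), the water channel gene Aqp1 2.36-fold (1.95 to 2.89) and Vsnl1 2.29-fold (2.03 to 2.58). The X-linked gene Xlr3b was 3.88-fold higher (3.06 to 4.95), 6330403K07Rik was 2.39-fold higher (1.97 to 2.91) and Gm20458 was 2.33-fold higher (1.90 to 2.91). Of the liver list, Ahsg was 2.21-fold higher (1.55 to 3.23), with 45 and 104 counts.

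Of 32 gene lists, 15 stood apart between the hearts. The erythroid list was lower in replicate 2, with a median log2 difference of -0.73 against -0.09 to 0.07 for random lists. Of its 16 members, 15 were lower there. The 4 adult haemoglobin genes lay between -0.90 for Hbb-bt and -0.87 for Hba-a1, while the embryonic Hbb-y was at -0.30, Hba-x at -0.42 and Hbb-bh1 at 0.15. The macrophage and leukocyte list was also lower in replicate 2, at -0.28 (random lists -0.10 to 0.13), although only 2 of 16 members, Csf1r at -0.39 and Cd68 at -0.45, were beyond the range of genes of like count, and Lyz2 and C1qb were at -0.12 and -0.13. DNA replication genes were at -0.16 (-0.07 to 0.04), with 19 of 20 lower but only 1 below the range of genes of like count. Fatty acid oxidation genes were at -0.13 (-0.07 to 0.03), with 19 of 22 lower. Of these 22 genes, 4 lay below the range of genes of like count and 1 above it. Calcium handling genes were at -0.10 (-0.08 to 0.04), with 12 of 15 lower, although this list fell inside the range with unmatched random lists and, at -0.07, after GC and length correction.

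The neural crest and neuron list had the largest difference towards replicate 2, a median of 1.24 (random lists -0.17 to 0.24), with 14 of 16 members higher, although only 8 of its 18 genes had a mean count of at least 50. Over the 8 members with a mean count of at least 100 the median was 0.48. The atrial list was higher in replicate 2 by 0.32 (-0.09 to 0.08), with 14 of 15 members higher, among them Myl7 at 0.43, Sln at 0.49 and Stard10 at 0.60. Of the 15, 8 lay above the range of genes of like count, while Nppa, at 0.07, lay within it. The ventricular list stood at -0.09 (-0.09 to 0.05) and inside its range. The ion channel and conduction list was higher by 0.24 (-0.08 to 0.08). Its members beyond the range of genes of like count included Shox2, Isl1, the pacemaker channel gene Hcn4 (0.88), Tbx3 (0.59), Cacna1d (0.49) and Cpne5 (0.43), while Gja1 was at -0.12. It shares Gja5, Kcnj3 and Kcnj5 with the atrial list. Stard10, Hba-x, Hbb-bh1, Csf1r, Cd68 and the channel and conduction genes after Isl1 were chosen for naming after their values were seen. Smaller median differences towards replicate 2 were seen for fibroblast and matrix genes (0.14), imprinted genes (0.13), epicardial genes (0.12), hypoxia genes (0.09), ribosomal protein genes (0.08, with 37 of 39 higher) and Notch, neuregulin and BMP signalling genes (0.08). Above the range of genes of like count were 0 of 39 ribosomal protein, 1 of 18 hypoxia and 2 of 15 epicardial genes. The same held for 5 of 16 imprinted and 4 of 22 fibroblast and matrix genes. Of the 20 Notch, neuregulin and BMP signalling genes, 3 were above and 1 below. The epicardial, hypoxia and Notch lists fell inside the range with unmatched random lists.

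The other lists lay inside the range of random lists, and the sign of several turned with the scaling. Their medians were -0.04 for sarcomere genes, 0.04 for cardiac transcription factors, -0.06 for endothelial and endocardial genes, 0.05 for cushion and valve mesenchyme, -0.05 for smooth muscle and pericytes and 0.02 for mitosis. They were -0.04 for the nuclear-encoded respiratory chain, -0.03 for mitochondrially encoded genes, -0.02 for glycolysis, -0.02 and 0.02 for genes that rise and fall with maturation, and 0.07 for immediate early and stress genes. The replication-dependent histones were at 0.24, the structural noncoding RNAs at -0.01, the liver list at -0.06 and the skeletal muscle list at 0.24. Some moved outside under single alternatives, namely sarcomere genes (-0.09) after GC and length correction and histones and skeletal muscle with unmatched random lists. Mitosis did so with TPM ratios, and immediate early genes at a mean count of at least 100. A median inside the range does not mean that no member differed. Of the 14 smooth muscle and pericyte genes, 4 lay above and 1 below the range of genes of like count.

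**Figure D3:**
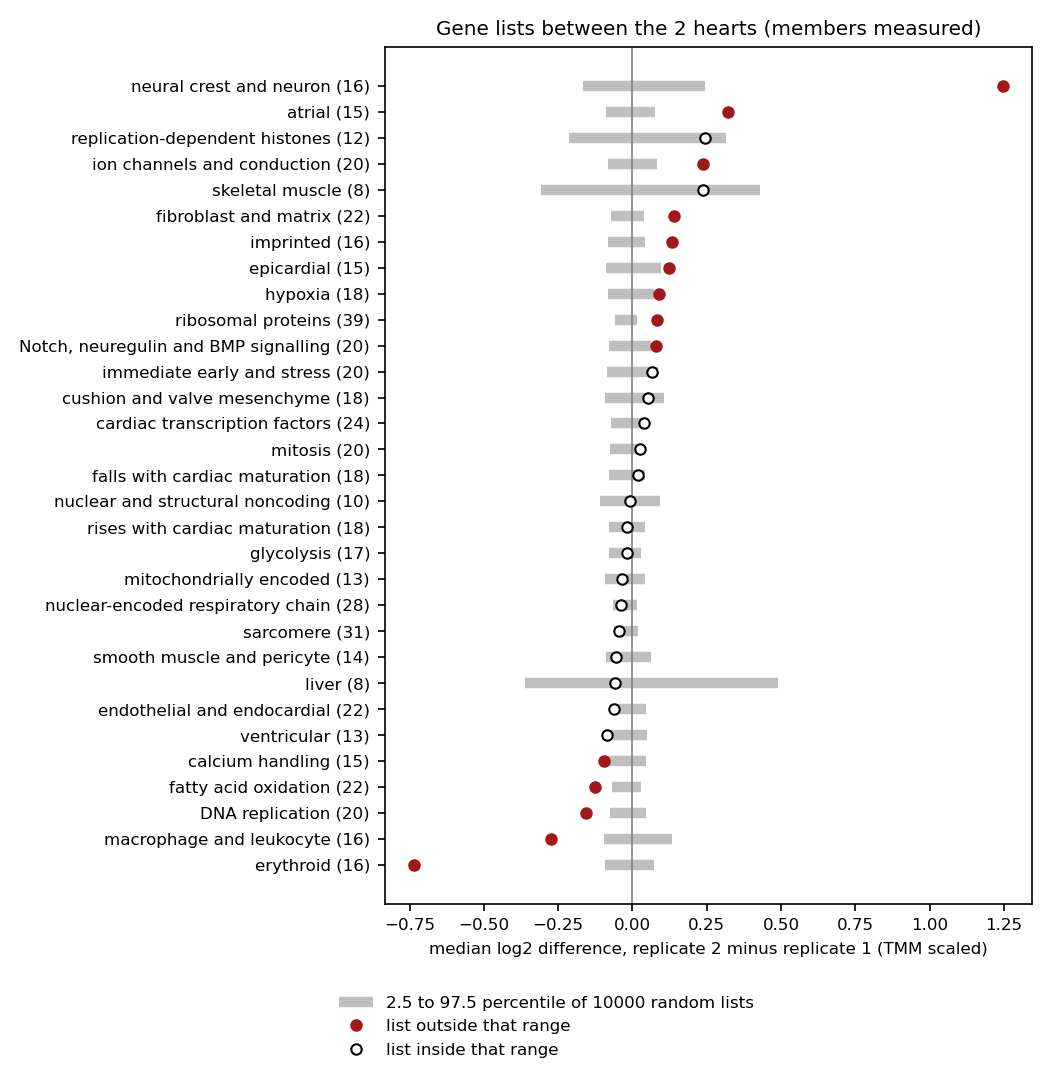
Median log2 difference, replicate 2 minus replicate 1, of 31 gene lists (points; filled where outside the range), with the central 95% range of 10000 random lists of like expression (grey bars) and the number of members measured. The neural list (1.24) and the erythroid list (-0.73) lie farthest from 0, and the sex-linked list is not drawn.

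**Figure D4:**
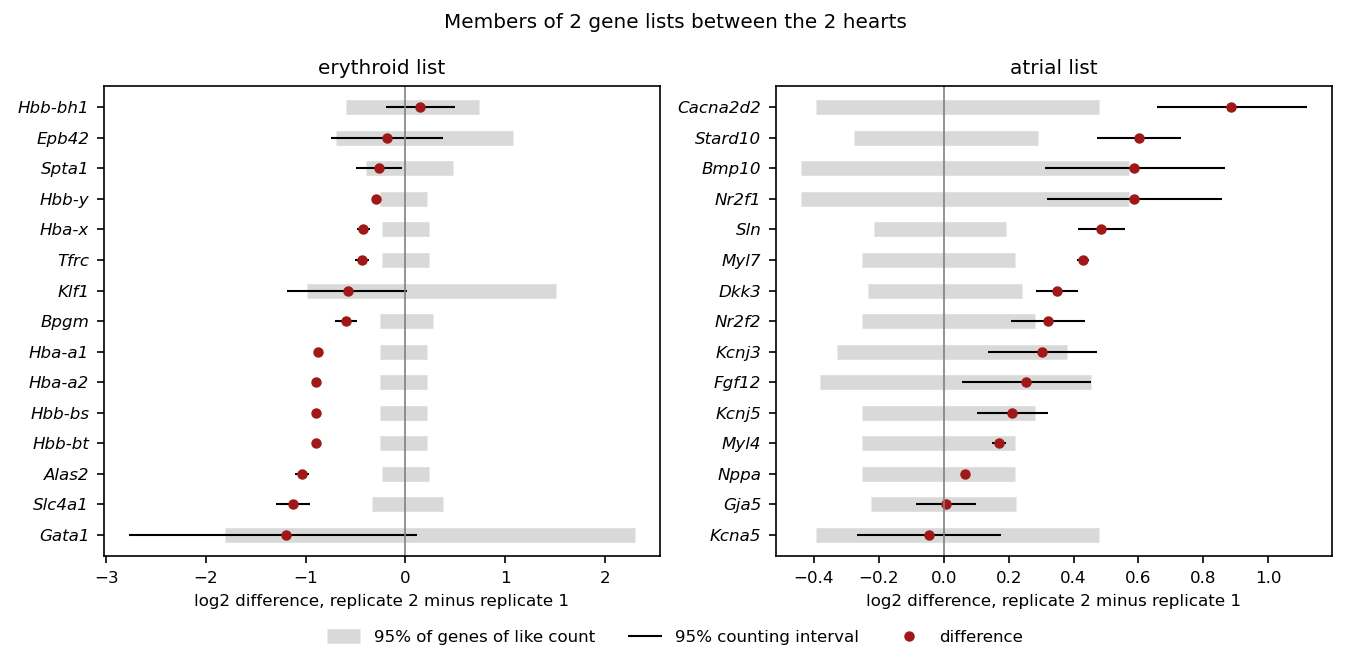
Log2 difference between the hearts of erythroid genes (left) and atrial genes (right), replicate 2 minus replicate 1, with its 95% counting interval (line) and the central 95% of genes of like count (grey). The adult haemoglobin genes cluster near -0.9 and Hbb-y is at -0.30, while 14 of 15 atrial genes lie above 0.

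The sex-linked list separated the libraries completely. Replicate 1 had 2310 counts of Ddx3y, 1845 of Eif2s3y, 1133 of Uty and 965 of Kdm5d, all on the Y chromosome, and replicate 2 had 0 of each. Set against the 3 counts that a count of 0 allows, these genes were at least 800-fold, 639-fold, 392-fold and 334-fold higher in replicate 1. Xist, the RNA that coats the inactive X chromosome (X, 103460366 to 103483254), had 15.7 counts in replicate 1 and 13912 in replicate 2, an 828-fold difference (515 to 1465). Usp9y and Zfy1 had 0 counts in both. The list's median, with genes at 0 set to their bound, was -8.62 (log2). Both libraries carry the same label of pooled sexes.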

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

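The rows of the gene tables that carry only a number, which no comparison used, held 24 estimated counts in replicate 1 and 22.8 in replicate 2. This is above the 3 counts that a count of 0 allows, in data outside the main measurement. The counts lay on 8 of the 26248 rows. The median length of these rows was 73 nt, and 26185 of them had an effective length of 0, so reads of this size range could hardly be assigned to them. No biological explanation was tested.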

How the results depend on the processing

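The alternatives without sex-linked, X and Y or haemoglobin genes, with posterior mean counts for the 2-fold genes, and with GC and length correction were chosen after seeing the data. The number of genes detected stayed within 1.5 times the main value under every alternative run (10083 to 18531, and 14091 to 14277 with 1 library alone), as did the detected list members (533; 526 to 544) and the pairs past the rule (21 to 22). FPKM and counts per kilobase give the pair ratios of TPM by construction. Of 66 values for single pairs under the other alternatives, 65 kept their side of the rule, and Myl7 over Myl2 (-0.46) did not in replicate 2 alone. The correlation of the libraries was 0.963 with a pseudocount of 0.1, 0.994 with no filter, 0.988 with FPKM and 0.990 at a mean TPM of at least 10. The coefficient of variation was 10.5% with no filter, 8.88% with posterior mean counts and 8.76% without haemoglobin genes, and the cause of these shifts was not tested. It was 8.25% without the sex-linked genes, of which only Xist had passed the filter. That fit held 15734 genes against 15735, so the shift came with the removal of Xist alone. The count of 2-fold genes moved with depth, to 659 (408 higher in replicate 2 and 251 in replicate 1) at a mean count of at least 10, and to 11 (5 and 6) at 500, where fewer low-count genes enter. Without X and Y genes, 9 genes were higher in replicate 1. The total of 51 was 52 to 62 under the other scalings, 64 with TPM ratios, 50 with posterior mean counts and 42 without X and Y genes. The other scalings move all genes and random lists alike, so the 15 lists standing apart could not change with them, and under the remaining alternatives 13 to 16 stood apart. Of 127 values for single lists under the latter, 116 kept their side of the range, and their direction where they stood apart, 5 fell back inside it and 6 moved outside. Of the lists standing apart, 1 changed sign, calcium handling, at 0.016 with spike-in scaling, which shifts all genes by 0.11 and left the list outside the range. Several lists inside the range changed sign too, mostly with spike-in scaling, and the liver list went from -0.06 to 0.35 with TPM ratios. The neural list was at 0.48 at a mean count of at least 100. Unmatched random lists took in the calcium handling, epicardial, hypoxia and Notch lists, so these rest on the choice of random list. GC and length correction took in calcium handling and moved the sarcomere and ventricular lists outside (both -0.09). Mitosis moved outside with TPM ratios (0.09), immediate early genes at a mean count of at least 100 (0.09), and histones and skeletal muscle with unmatched lists. The spike-in SD was 0.11 at 100 counts and 0.53 with no minimum. The haemoglobin share was 1.75% of counts on average (1.26% to 2.24% with 1 library alone), 4.79% of TPM and 4.79% of FPKM, since these genes are short. Of the other values without a test, 16 of 68 list medians, 3 of 20 isoform shares and 0 of 16 shares of counts moved by less than the SD between the libraries under another unit or scale. Leaving out a library is not possible for values that compare the 2. Depth limits genes below about 100 counts, and 1 library per embryo limits all differences.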

Other observations

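The tests below were chosen only after the patterns were seen, and for those on GC and length, on low counts and on X-linked genes the prediction was written before the tested value was seen. The differences in this paragraph were chosen after seeing the values, from no fixed list. Along with Spp1, Gpnmb and Lgals3, the macrophage protease gene Mmp12 was lower in replicate 2, at -2.07 with 46 and 11 counts, while Trem2 (-0.60), Ctsk (-0.01), Cd63 (0.06) and Cd9 (-0.01) were within the range of genes of like count. The maternally expressed noncoding RNAs Meg3 (0.57), Rian (0.31) and Mirg (0.49) of 1 imprinted cluster, and its paternally expressed gene Dlk1 (0.35), were higher in replicate 2, Mirg within the range of genes of like count. The proteasome gene Psmd13 (1.05) and the endosomal gene Rab5c (1.00) were about 2-fold higher there without other members of those complexes having been tested. The X-linked processed pseudogene Rpl30-ps10 had 0 counts in replicate 1 and 269.5 in replicate 2, at least 86.5-fold higher against 3 counts. A fractional estimate arises where reads are shared with other genes, and that split was not examined for this gene. Beside the neural list, Ahsg of the liver list (45 and 104 counts) and the epithelial genes Epcam (3 and 54 counts) and Cdh1 (17 and 58 counts) of the lung list were higher in replicate 2. The liver list as a whole was at -0.06, with 5 of 8 members lower there, and these values do not decide whether the neuronal transcripts came from ganglia of the heart or from tissue next to it.

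The erythroid list was lower in replicate 2. Removing the trend with GC content and transcript length left its median at -0.78, and the 9 members that are not haemoglobin genes had a median of -0.59, against -0.14 to 0.17 for random lists. This argues against GC or length as the whole cause. Reads shared among globin genes would leave the sum of those genes unchanged. The haemoglobin genes together held 2.24% of counts in replicate 1 and 1.26% in replicate 2, which argues against such sharing as the cause of their drop. Less blood of the same makeup would lower adult and embryonic haemoglobin genes alike. The embryonic genes stood 0.60 above the adult ones, beyond the -0.19 to 0.23 of random gene sets. Those sets draw genes independently, while the adult genes are near-identical pairs that share reads, so this range understates the spread. The median of the 3 embryonic genes was lower as well, at -0.30 (random sets -0.19 to 0.19). Of these genes Hbb-y and Hba-x were lower in replicate 2, while Hbb-bh1 was higher. Less blood as a part of the difference stays open. Sex, collection day and other differences between the embryos, such as development or dissection, cannot be told apart as its origin.

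The atrial list was higher in replicate 2. Members with at least 500 counts had a median of 0.31 and the list after GC and length correction one of 0.33, against at most 0.06 and 0.07 at the upper end of random lists, which argues against low counts or base composition. The ventricular list was at -0.09, inside its range before and outside it after that correction. The share of atrial tissue kept at dissection, development, sex and collection day stay open and were not tested.

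The sex label of both libraries is a pool of male and female. If each library held both sexes, both would contain Xist, but the lower Xist level was 0.117% of the higher. The 4 Y-linked genes of the sex-linked list with counts were at least 334-fold apart, as a single male embryo for replicate 1 and a single female embryo for replicate 2 would give, and the same labels describe each sample as a single heart. The whole Y chromosome had 6288 and 6 counts, and the 6 lay on Gm37158 (3 and 4 counts) and Gm20826 (1 and 2 counts), which had like counts in both libraries. The label may therefore describe the donors of the experiment rather than each library.

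Outside the fixed lists, 6 genes on the X chromosome that are known to escape X inactivation had a higher median in replicate 2, the library with Xist. Eif2s3x was at 0.64 (log2), 5530601H04Rik at 0.63, Kdm5c at 0.56, Kdm6a at 0.52 and Pbdc1 at 0.42, while Ddx3x, at 0.18, was within the range of genes of like count. Their median of 0.54 lay outside the -0.12 to 0.09 of random lists. The 414 X-linked genes other than Xist with a mean count of at least 100, these included, had a median of -0.00476, inside the range of matched gene sets (-0.02 to 0.01), so no difference of the X chromosome as a whole was detected.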
